A study of Mus musculus with 6 samples.

How the data were processed

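The values are the deposited log2 ratios of 6 two-colour spotted oligonucleotide arrays, each comparing RNA of a single mutant cortex with RNA of a single wild-type cortex of E12.5 mouse embryos. RNA was extracted with Trizol, per the labels' protocols. The scanner software, background treatment, spot filters and normalization are not given in the sources used here. The direction and scale of the deposited values are not stated either. They were read as log2 of Cy5 over Cy3: they lie on both sides of 0, the highest value, 16.61, equals log2 of 1e+05, and the probe of the targeted gene Mest had deposited values of -1.10, -1.02 and -1.21 on the arrays with the mutant in Cy5 and 1.49, 1.49 and 1.73 on those with the mutant in Cy3. The deposited values correlated over probes at 0.17 to 0.35 within dye orientations and at 0.12 to 0.41 between them. Ratios already turned could give this too, so it does not settle the direction, which rests on Mest. The deposited log2 ratios were not centred, with medians of 0.26, 0.76, 0.19, -0.004, -0.59 and 0.28 on arrays 1 to 6, so that both the scale and the direction rest on the values and the dye labels, and any processing before deposit stays unknown.

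The ceiling value was treated as missing (590 values), as were empty entries. The 232 control spots for Gapdh were left out of the tests. Between 75.4% and 89.9% of probes had a value on an array. No spot intensity was used here, so dim and saturated spots could not be told from others, a ratio of a saturated spot is pulled towards 0, and intensity-dependent (loess) normalization could not be applied. This can leave offsets that depend on brightness in the ratios. The precision is set by the number of arrays.

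Each ratio was turned to mutant over wild type and each array was centred on the median of its probes. Probes with a value on at least 4 arrays, and at least 2 per dye orientation, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with an intercept for genotype and a term for dye orientation, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The wild-type cortex shared by 2 arrays was a random block (duplicateCorrelation, consensus correlation 0.25). The label of array 1 names wild type 1, while the design text lists wild types 2, 8 and 9. It was read as wild type 2, so that arrays 1 and 4, 2 and 5, and 3 and 6 formed blocks. The mutants are separate embryos, and the spread over arrays contains that of mutants, of wild types and of the hybridisation.

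Gene names came from the array platform's annotation, which is old, through Entrez identifiers, with symbols looked up in the gene table of assembly GRCm38.p6, where 16184 of 17003 annotated probes matched and 0 symbols changed. Of the probes on the array 16632 had 1 gene symbol, 139 several and 4995 none. Of 776 genes with over 1 tested probe, 419 had probes of opposite sign. Gene lists used 1 value per gene, the mean of its probes. The lists and the planned tests were fixed before the data were examined, but the set test departs from the plan, which named camera with a preset inter-gene correlation of 0.01 on ratios whitened for the block. The main values come from cameraPR, limma's competitive set test for ranked statistics, on the z-scores of the blocked fit with the same preset correlation. This version of camera was used so that genes with a missing value could enter. Beside it, camera as planned (run after the data were seen), camera with an estimated correlation and fry, which tests whether genes move on balance one way, were run on the genes with values on all arrays.

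The rule for naming genes was fixed at the same time. It named Mest, then up to 12 probes per direction past the adjusted threshold and with the same sign on every array, then, as none passed, the 6 with the smallest p per direction, up to 4 members with the smallest p of each list, Xist and the Y-linked genes, and at most 2 unnamed probes per direction. Single values used exact sign-flip permutation tests, two-sided.

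The fit was tested on 3 simulated datasets of 17476 probes with 100 probes changed by each of log2 1 and 2. They used the moderated SDs, the block correlation and the dye effects of the data, with normal noise independent between probes. Of the changed probes 98.7% and 100% had the right sign, 9 unchanged probes were called per dataset on average, and 5.09% of unchanged probes had an unadjusted p under 0.05. Alternatives covered the block, the dye term, centring, scaling and quantile normalization, missing values, robust eBayes, the threshold, 1 value per gene, single arrays, pairs of arrays and dye orientations left out, and an ordinary test with neither moderation nor the block. After the data were seen, a fit without moderation that keeps the block, centring on Gapdh control spots, the Xist ratio as a covariate and the removal of 1570 probes with at least 2 values that equal, to the third decimal, the log2 of a ratio of whole numbers up to 10 were added. By that criterion 5 of the 232 control spots would also be removed.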

Results

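The arrays measured which transcripts differ in the embryonic mouse cerebral cortex when the active copy of Mest, also called Peg1, is disrupted. Mest encodes a protein of the alpha/beta hydrolase fold family and is imprinted, so that the copy inherited from the father is the one expressed. Mutant embryos received from the father a LacZ-targeted allele that lacks exons 3 to 8. At stage E12.5, RNA of 6 single mutant cortices was hybridised on 6 two-colour oligonucleotide arrays, each against RNA of a single wild-type cortex. The mutant was labelled with Cy5 on 3 arrays (mutants 3, 5 and 6) and with Cy3 on the other 3 (mutants 1, 4 and 7). The design names 3 wild-type cortices, and each was taken as used on 2 arrays, once per dye, although the wild-type label of the array of mutant 3 is not among the 3 names. Between 16422 and 19564 of the 21766 probes had a value on an array, and 17476 probes entered the tests, with 12588 genes in those of gene lists. All values below are log2 ratios of mutant over wild type, with the median of each array set to 0. The number of arrays limits the precision, and no signal level was used here.

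Mest was the transcript with the smallest p of all 17476 probes, and it was lower in every mutant. Its fitted log2 ratio was -1.59 with a standard error of 0.13 and a 95% confidence interval from -1.91 to -1.27, a level 3.01-fold lower (2.42-fold to 3.76-fold) than in wild-type cortex. Mutants 3, 5 and 6 gave -1.36, -1.78 and -1.39, and mutants 1, 4 and 7 gave -1.50, -2.07 and -1.44 (SD 0.28, n = 6). An exact sign-flip permutation test over the 6 arrays gave a two-sided p of 0.0313, the smallest that 6 arrays allow. The arrays share wild-type cortices, and over 3 independent wild types the smallest p would be 0.25. Adjusted over all probes, Mest did not pass the threshold (limma, adjusted p = 0.60, lower on 6 of 6 arrays). The array carries 1 tested Mest probe, whose position relative to exons 3 to 8 was not determined here. The direction of the deposited ratio was read from this gene, whose deposited sign followed the dye orientation on all 6 arrays. The lower level of Mest in every mutant is therefore part of that reading. Neither it nor the sign-flip p tests the direction.

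**Figure D1:**
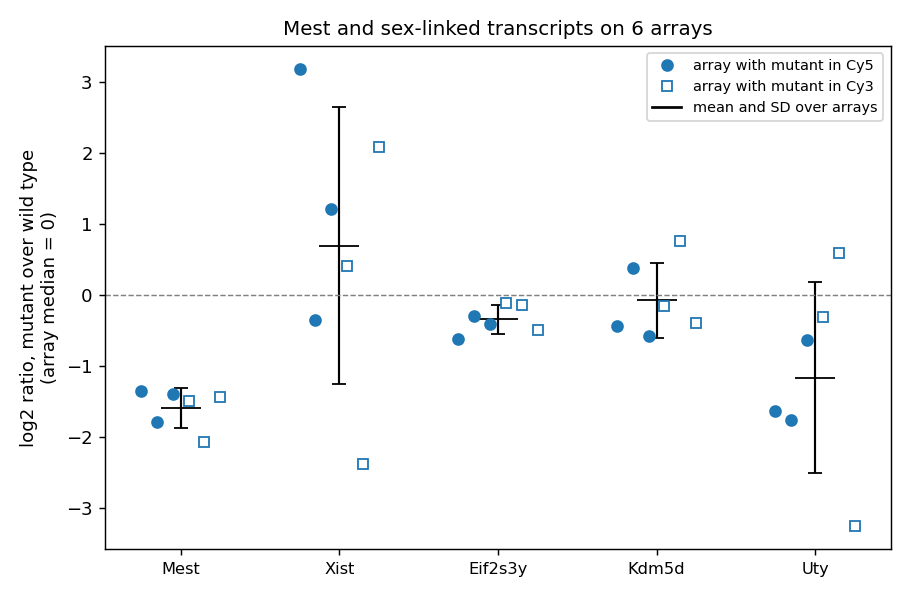
Log2 ratios of mutant over wild type on each array (vertical axis, array median at 0) for Mest, Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty. Each symbol is 1 array, filled for the mutant in Cy5 and open for the mutant in Cy3, and black bars give the mean and SD over 6 arrays. Mest lies between -2.07 and -1.36 on all arrays, while Xist ranges from -2.38 to 3.18.

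Apart from Mest, the single probes with the smallest p among those with 1 gene name and the same sign on every array with a value were a mixed group, and none of them passed the adjusted threshold. Among those higher in mutants, Agpat3, an acyltransferase of phospholipid synthesis, had a log2 ratio of 2.57 (standard error 0.28) on 5 arrays, and 1110058D11Rik had 1.76 (standard error 0.18) on 4. The calpain protease gene Capn8 lay at 0.69 on 5 arrays, and the myeloid receptor gene Trem3 and the membrane protein gene Tmem63a lay at 0.37 and 0.38 on all 6. Among those lower in mutants, A430102A20Rik had -2.42 (standard error 0.18) and the voltage-gated potassium channel gene Kcnc1 -2.34 (standard error 0.26), each on 4 arrays. Zfp821, a zinc finger gene, lay at -1.59 on 5 arrays and Pgc, which encodes the stomach protease precursor progastricsin, at -1.15 on 4. Of the 12 genes named here beside Mest, 9 had values that did not overlap between the dye orientations, all except Agpat3, A430102A20Rik and Cfap57, against 29.8% of all 17476 probes and 11.7% of the 973 with the same sign on every array with a value. Ranking by p in a fit with a dye term favours such probes, so this share is a description and no test. Zfp821 had -0.23, -0.34 and -0.29 with the mutant in Cy5 against -2.33 and -3.45 in Cy3, and Pgc had -2.07 and -1.92 in Cy5 against -0.11 and -0.48 in Cy3. The death receptor ligand gene Fasl lay at -1.26 and the cilium gene Cfap57 at -0.59, both on 6 arrays. A probe annotated as Tcrb-V8.2 had 1.92 on 4 arrays (3.65 and 2.98 with the mutant in Cy5, 0.64 and 0.42 in Cy3), but 139 other tested probes carry the same name, of which 63 lay below 0 and 76 above, so its gene is uncertain.

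No probe passed an adjusted p of 0.05 in limma, and the 12 genes named above beside Mest each had an adjusted p of 0.90, with the same sign on every array with a value. At an unadjusted p under 0.05 there were 687 probes, 280 higher and 407 lower in mutants, where 874 would be expected by chance, and without variance moderation 0 were called after adjustment too, with 902 at the unadjusted threshold, or 1341 where the shared wild types were not modelled either. The split depended on the centring: without it 179 were higher and 44 lower, and with arrays centred on the Gapdh control spots 2671 were higher and 90 lower. Of 3703 tested probes without a single gene name (none or several), 159 had an unadjusted p under 0.05. They included CG_Mm_EXT_3101999_1 and CG_Mm_EXT_3110009_1 with 1.19 and 0.84, and CG_Mm_EXT_3104705_1 and CG_Mm_EXT_3109804_1 with -1.20 and -0.50. Simulated data had the same number of probes, each with its SD after moderation and with normal noise independent of other probes. Rates in real data may therefore differ. In the simulated data 41 of 100 probes changed by 1 on the log2 scale and 72 of 100 changed by 2 were called. Counting only p-values small enough to pass if a single probe had changed, these numbers were 0 and 28.7 on average.

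**Figure D2:**
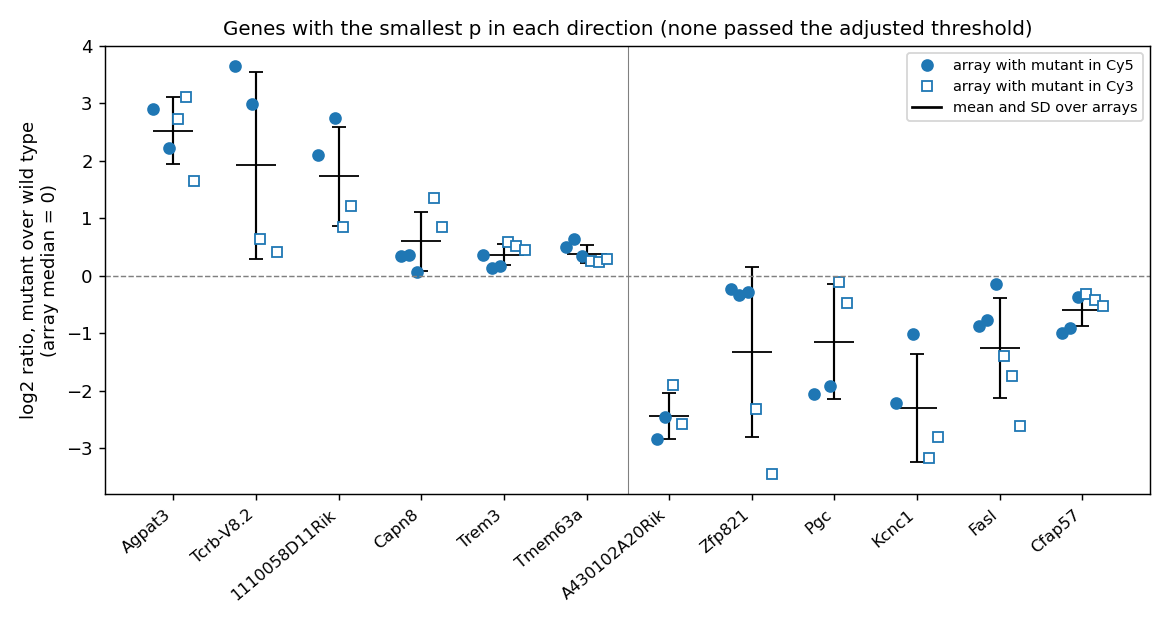
Log2 ratios of mutant over wild type per array (vertical axis, array median at 0) for the 6 named genes with the smallest p in each direction apart from Mest. Each symbol is 1 array and black bars give the mean and SD. Agpat3 reaches 3.12 and A430102A20Rik -2.85, several genes lack values on 1 or 2 arrays, and none passed the adjusted threshold.

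Of the 22 gene lists fixed before the data were examined, those of ribosomal proteins and of red blood cell genes were lower in mutants by a competitive test with a preset correlation, but neither was called with an estimated correlation (limma camera, adjusted p = 0.71 for each). The 66 ribosomal protein genes averaged -0.22 ± 0.12 (SD, n = 6 arrays), lay below 0 on all 6 arrays, and 63 of the 66 had a ratio below 0. Rpl10, Rps20, Rpl34 and Rps3 lay at -0.25, -0.36, -0.35 and -0.24. The members named here and for the lists below are those with the smallest p of each list. The 13 erythroid genes averaged -0.20 ± 0.22 (SD, n = 6 arrays), below 0 on 5 of 6 arrays, with 10 of 13 below 0. The embryonic globin genes Hbb-bh1, Hbb-y and Hba-x lay at -0.36, -0.42 and -0.23, and Alas2, which encodes the erythroid enzyme that starts haem synthesis, at -0.24. Control spots for the glycolytic gene Gapdh moved the same way, with a mean of -0.26 ± 0.18 (SD, n = 6 arrays) and values below 0 on all 6 arrays (exact sign-flip permutation p = 0.0313, the smallest that 6 arrays allow, where 3 independent wild types would allow 0.25). The preset test gave adjusted p = 2.75e-18 for the ribosomal list and 0.00764 for the erythroid list (limma cameraPR), and camera on the genes with values on all arrays, named in the plan but run after the data were seen, gave 1.38e-19 and 0.00314. Both preset a correlation of 0.01 between genes, whereas the estimates were 0.46 for the ribosomal and 0.072 for the erythroid list. These p-values do not allow for correlation that large. No member of either list passed the threshold over all genes or adjusted over the list alone. The erythroid call ended without mutant 1 (mean -0.17, limma adjusted p = 0.21), without the arrays of wild type 2 (-0.093, 0.64), with the mutant in Cy5 only (-0.29, 0.39) or Cy3 only (-0.095, 0.36) and without centring (adjusted p = 0.17), and with arrays not centred the means were 0.025 for the ribosomal and 0.070 for the erythroid list and -0.0084 ± 0.31 for Gapdh control spots, where the median of all probes was 0.26. Centred on the Gapdh control spots, the means were 0.032 and 0.067, so that both lists were lower only relative to the other probes of an array.

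**Figure D3:**
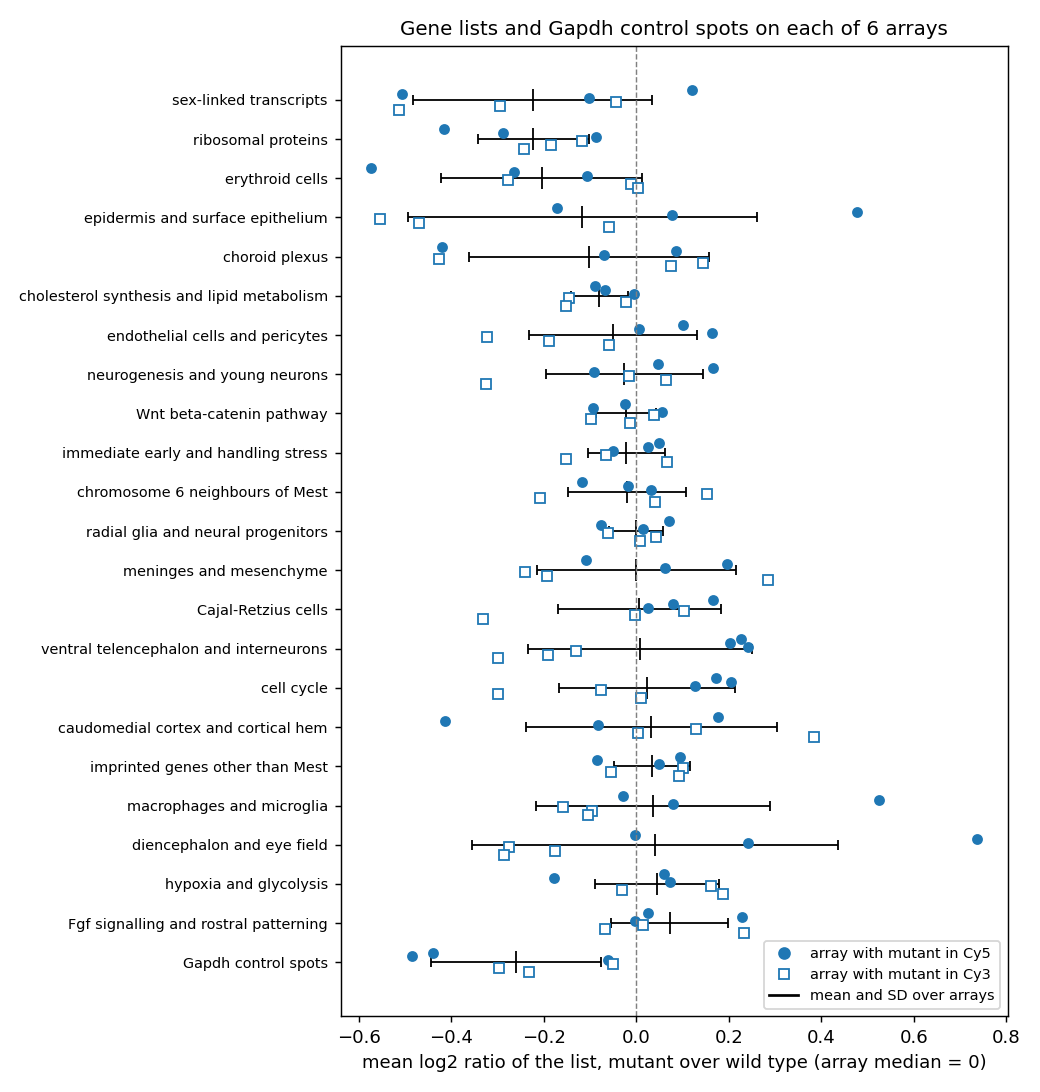
Mean log2 ratio of mutant over wild type (horizontal axis, array median at 0) of each of 22 gene lists and of the Gapdh control spots. Each symbol is 1 array, filled for the mutant in Cy5 and open for the mutant in Cy3, and black bars give the mean and SD over 6 arrays. Ribosomal protein genes, the cholesterol and lipid list (not called) and Gapdh control spots lie below 0 on every array with this centring, while the ribosomal mean was 0.025 without centring, and most other lists span 0.

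The lists of genes that pattern the cortex had means within 1 SD of 0 over arrays. So did the erythroid list (-0.20 ± 0.22), so that this criterion does not show the absence of a change. The Fgf signalling and rostral patterning list (17 genes measured) averaged 0.072 ± 0.13 (SD, n = 6 arrays), with Fgf15 at 0.14, Fgfr2 at 0.16, Spry4 at 0.36 and Fgf8, the signal of the rostral organiser, at -0.15. The caudomedial cortex and cortical hem list (19 genes) averaged 0.033 ± 0.27, with Nr2f1, a transcription factor of caudal cortex, at 0.34, Gli3 at 0.25, and Bmp7 and Rspo1 at 0.10 and 0.096. In the Wnt beta-catenin list (32 genes, -0.022 ± 0.064), Tcf7l2, a transcription factor of the pathway, lay at 0.55 with a standard error of 0.14 and was above 0 on 6 of 6 arrays. Its adjusted p in limma was 0.35 over the list alone and 0.90 over all genes. Fzd3, Dvl1 and Gsk3b lay at 0.28, -0.34 and 0.16. Dvl1 had 0.27, -0.07 and 0.19 with the mutant in Cy5 against -0.45, -0.655 and -1.30 in Cy3. Among the Fgf genes above, Spry4 had 1.10, 1.77 and 0.22 in Cy5 against 0.078, -0.14 and -0.87 in Cy3.

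Lists of progenitor and neuronal markers also had means within 1 SD of 0. Radial glia and neural progenitor genes (24 measured) averaged -0.0003 ± 0.058, with Hey1, Slc1a3, Fabp7 and Sox3 at -0.18, 0.39, -0.20 and 0.60. Sox3 had values on 5 arrays, of which 3 agreed in sign. Genes of neurogenesis and young neurons (31 measured) averaged -0.026 ± 0.17, with Map2, Stmn1, Tbr1 and Neurog1 at -0.19, -0.30, -0.13 and 0.26. Cajal-Retzius genes (9 measured) averaged 0.0062 ± 0.18, with Trp73, Nhlh2, Calb2 and Lhx1 at 0.13, -0.16, -0.084 and -0.18. The cell cycle list (30 genes) averaged 0.023 ± 0.19, with Tyms, Kif20a, Ccne2 and Rrm2 at 0.46, 0.21, 0.21 and 0.24. Ventral telencephalon and interneuron genes (16 measured) averaged 0.0085 ± 0.24. In this list and in 4 others (cell cycle, diencephalon, endothelial and macrophage genes), all 3 arrays with the mutant in Cy5 lay above all 3 with the mutant in Cy3. The ventral members Dlx5, Isl1, Gsx1 and Dlx6 had 0.27, -0.17, 0.14 and 0.092. None of these lists was called by any of the set tests with arrays centred on their medians, while the cell cycle list was called when arrays were centred on Gapdh control spots (mean 0.27, limma adjusted p = 0.042), and no member passed the threshold over all genes or adjusted over the list alone.

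Imprinted genes other than Mest and genes next to it on chromosome 6 did not pass either. The 38 imprinted genes averaged 0.033 ± 0.082 (SD, n = 6 arrays), with Snrpn, Rian, Igf2r and Calcr at -0.22, 0.73, 0.15 and 0.15. Rian ranged from -0.69 to 2.21 over arrays. Among 29 neighbours of Mest (-0.020 ± 0.13), Nrf1, a transcription factor for mitochondrial genes, lay at 0.24 with a standard error of 0.069 and above 0 on 6 of 6 arrays (limma, adjusted p = 0.46 over the list alone). Irf5, Klhdc10 and Podxl lay at 0.23, 0.19 and -0.17. The list of cholesterol synthesis and lipid metabolism (23 genes) averaged -0.080 ± 0.061 over arrays, below 0 on all 6, but its median gene lay at -0.0021, with 11 genes above and 12 below 0, and it was not called (limma cameraPR, adjusted p = 0.94). In it Srebf2 lay at -1.47 on 5 arrays, of which 3 agreed in sign, Mvd at -0.32, Scd2 at -0.076 and Srebf1 at 0.14. Srebf2 had -2.76, -4.62 and -1.93 with the mutant in Cy5 against 0.65 and 0.10 in Cy3. On the Cy5 arrays the list means of -0.088, -0.068 and -0.0045 depended on Srebf2 for their sign. Hypoxia and glycolysis genes (23 measured) averaged 0.045 ± 0.13, with 12 above and 11 below 0. P4ha1, Hk1, Hif1a and Hk2 lay at 0.27, 0.81, 0.19 and 0.20, and Hk1 ranged from -0.099 to 2.24 over arrays. Immediate early and handling stress genes (22 measured) averaged -0.021 ± 0.083, with Fosb, Zfp36, Btg2 and Egr2 at -0.77, -0.22, 0.28 and 0.31.

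Markers of tissues next to the cortex gave no call. Choroid plexus genes (6 measured) averaged -0.10 ± 0.26, with the transthyretin gene Ttr at -0.34, Aqp1 at 0.088, Folr1 at -0.056 and Kcne2 at -0.23. Diencephalon and eye field genes (17 measured) averaged 0.040 ± 0.40, with Irx1, Pax2, Pmel and Gbx2 at -0.24, -0.64, -0.18 and 0.35. Pax2 and Gbx2 had values on 4 arrays each and changed sign with the dye orientation. Pax2 had 0.35 and 0.062 with the mutant in Cy5 against -2.12 and -0.96 in Cy3. Gbx2 had 1.45 and 0.84 in Cy5 against -0.82 and -0.07 in Cy3. Endothelial and pericyte genes (17 measured) averaged -0.051 ± 0.18, with Esam, Kdr, Plvap and Tie1 at -0.43, -0.21, -0.35 and 0.085. Plvap had 0.49, -0.09 and 0.83 in Cy5 against -1.12, -0.74 and -1.46 in Cy3. Meningeal and mesenchymal genes (21 measured) averaged -0.0002 ± 0.21, with 12 above and 9 below 0. Mgp, Postn, Crabp2 and Col6a2 lay at -0.24, -0.54, -0.13 and -0.27. Epidermal genes (12 measured) averaged -0.12 ± 0.38, with Krt18, Tfap2a, Perp and Trp63 at -0.68, -0.21, -0.21 and -0.87. The dye orientations disagreed in sign for Trp63, with 1.03 and 0.23 in Cy5 against -3.69, -3.03 and -0.068 in Cy3. They also did for Tfap2a, with -0.53, -0.74 and -0.68 in Cy5 against 0.16, 0.44 and 0.073 in Cy3. Macrophage and microglia genes (14 measured) averaged 0.036 ± 0.25, with Tyrobp, Aif1, C1qc and Cx3cr1 at -0.089, -0.087, 0.071 and 0.12. Over the uncalled lists the mean over genes, the median and the direction of the test did not share a sign for the imprinted, Wnt, radial glia, Cajal-Retzius, diencephalon and endothelial lists, nor for the meningeal list.

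The single embryos on an array often differed in sex-linked transcripts. Xist, the RNA expressed from the inactive X chromosome of females, had ratios of 3.18, -0.36 and 1.21 on the arrays of mutants 3, 5 and 6, and of 0.41, -2.38 and 2.09 on those of mutants 1, 4 and 7. The mean of the Y-linked genes Kdm5d, Uty and Eif2s3y was -0.90, -0.56, -0.54, -0.20, 0.40 and -1.38 in the same order, opposite in sign to Xist on all 4 arrays where Xist was beyond 1 in size. Eif2s3y lay at -0.35 and below 0 on 6 of 6 arrays, with a limma adjusted p of 0.072 over the list alone. The fitted ratios of Xist, Uty and Kdm5d were 0.69, -1.17 and -0.074, and the list of 4 sex-linked genes averaged -0.22 ± 0.26. Where Xist was beyond 1 in size, it was higher in mutants 3, 6 and 7 and lower only in mutant 4. The fitted ratios of these genes, Eif2s3y included, therefore cannot be told apart from an imbalance of sex between mutants and wild types.

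The dye term passed for 47 probes, where the genotype term passed for 0. Each block pairs opposite dye orientations, so the fit gives the dye term more precision than the genotype term. The counts are therefore not like for like. These 47 passed an adjusted p of 0.05 for the dye term (limma), 1 with a positive and 46 with a negative coefficient, but the number ranged from 0 to 26 when any 1 array was left out, was 1 when the shared wild types were not modelled, and was 135 with values on all 6 arrays, 150 after quantile normalization, 176 with scaling and 658 without centring. The median size of the dye coefficient over probes was 0.17, against 0.14 for the genotype coefficient. Across probes, which are not independent replicates, ratios of mutant over wild type correlated between 0.17 and 0.35 for arrays of the same dye orientation and between -0.41 and -0.12 for arrays of opposite orientation. The median SD of a probe over the arrays was 0.41.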

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

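The tests on Gapdh control spots, on blood and on Xist were chosen only after the results were seen, while the test on other abundant transcripts was set before its result. Of 124 values compared over 4 to 6 arrays (named genes, list members, list means and Gapdh control spots), 5 had an array far from the others, where chance gives about 1 in 20. On the array of mutant 5, the macrophage and microglia list had a mean of 0.52 against -0.16 to 0.080 on the other arrays, Egr2 had 1.25 against 0.002 to 0.33, and Nhlh2 had -0.71 against -0.14 to 0.14. Zfp36 had -0.70 on the array of mutant 6 against -0.24 to 0.018 on the others. The Cajal-Retzius list had -0.33 on the array of mutant 7 against -0.0033 to 0.17.

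With arrays centred on their medians, ribosomal protein genes were lower in mutants on all 6 arrays, and so were Gapdh control spots, whereas without centring the ribosomal mean was 0.025. An offset of bright spots is a candidate explanation: the ribosomal mean minus that of the Gapdh control spots was 0.038 ± 0.099 (SD, n = 6 arrays), and 56 other abundant transcripts averaged -0.098 ± 0.060, below 0 on all 6 arrays. The brightness of these spots was assumed, since no signal level was used. The ribosomal means were -0.42, -0.29 and -0.087 with the mutant in Cy5, and -0.12, -0.18 and -0.24 in Cy3. The Gapdh control spots had -0.44, -0.49 and -0.06 in Cy5, and -0.05, -0.30 and -0.23 in Cy3. An offset tied to the same dye on every array would change sign between orientations, so these values argue against that form. An offset that differs between arrays or follows the sample stays open. The 56 transcripts came from a list of genes taken as abundant. The ribosomal list still lay below those transcripts by a mean of -0.12 ± 0.071, on 6 of 6 arrays, so that a brightness offset of one size for all abundant transcripts would leave part of it. Because Gapdh and ribosomal protein transcripts could also both be lower in mutant cortex, a biological difference stays open and was not tested separately.

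Erythroid genes were lower on 5 of 6 arrays, and less blood in the mutant cortices is a possible explanation, as is the same brightness offset. The list lay 0.056 ± 0.22 above the Gapdh control spots and -0.11 ± 0.19 relative to other abundant transcripts (SD, n = 6 arrays). The first value meets the criterion set for a brightness offset, within 1 SD of 0 or above, and the second meets neither that for less blood, over 1 SD below, nor that against it. A further rule, that the spread must be smaller than the shift of the list itself, was added after these values were seen, and by it the first value does not decide either. With these arrays neither explanation is excluded.

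Xist lay beyond 1 in size on 4 arrays, and on all 4 the Y-linked mean had the opposite sign, which is consistent with embryos of different sex on those arrays, although on the array of mutant 4 Eif2s3y had the sign of Xist (-0.14 and -2.38). Leaving those arrays out would keep 2, so that a fit without them was not run. With the Xist ratio as a covariate no probe passed the adjusted threshold either, and 1399 passed an unadjusted p of 0.05. The sex of the embryos is not given in the sources used here.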

How the results depend on the processing

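Centring on Gapdh control spots, the Xist covariate, the removal of probes with small whole-number ratios and the fit without moderation that keeps the block were added after the data were seen, as was the run of camera on whitened ratios, and the other alternatives were fixed before. No probe passed the adjusted threshold in any of the 29 alternatives that give this count, and Mest was lower and did not pass in any of them, from -1.78 to -1.33, with limma adjusted p from 0.107 to 0.999. Probes with an unadjusted p under 0.05 numbered 687, but 1119 without the block, 1073 without the dye term, 223 without centring, 1341 with neither moderation nor the block (902 without moderation alone), 2761 centred on Gapdh control spots, 1399 with Xist as covariate, 1537 with the mutant in Cy5 only and 2038 in Cy3 only. They numbered 421 and 393 without the arrays of wild types 2 and 8, and 350 to 834 without 1 array, with 389 without mutant 3 and 350 without mutant 7. Probes with a dye effect numbered 47, but 1 without the block or with Xist as covariate, 658 without centring, 176 with scaling, 150 after quantile normalization, 135 with values on all 6 arrays, 2 without a filter on missing values, 402 at an adjusted p of 0.10, 19 with 1 value per gene, 10 centred on Gapdh control spots, 0 without moderation, with or without the block, 0 without the arrays of any 1 wild type, and 0 to 26 without 1 array. The cause of these moves was not tested, except that fewer arrays entered where arrays were left out. With the mutant in Cy5 only or in Cy3 only no dye term could be fitted. Counts and list means from those fits therefore do not separate genotype from dye. Centring on Gapdh control spots moved the median of all probes to 0.26, so that more probes lay above 0.

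The ribosomal list, at -0.23 over genes, kept its call with a preset correlation under the alternatives of centring, block, filter and arrays, but turned to 0.025 without centring and to 0.032 centred on Gapdh control spots, where the median of all probes lay at 0.26. The erythroid list, at -0.19, turned to 0.070, where it lost its call (adjusted p = 0.17), and to 0.067, where it kept one relative to other genes (adjusted p = 0.042). It also lost its call without the arrays of wild type 2 (-0.093, adjusted p = 0.64), with the mutant in Cy5 only (-0.29, adjusted p = 0.39) and in Cy3 only (-0.095, adjusted p = 0.36), and ranged from -0.24 to -0.13 without 1 array, losing its call without mutant 1 (-0.17, adjusted p = 0.21). With an estimated correlation (adjusted p = 0.71) and with fry (adjusted p = 0.27) both lists lost their calls at the values of -0.23 and -0.19, and camera with a preset correlation on whitened ratios kept both (adjusted p = 1.38e-19 and 0.00314). The cell cycle list was called higher (0.27, adjusted p = 0.042) when centred on Gapdh control spots, where the median of all probes lay at 0.26, and the reason was not tested. The probe named Tcrb-V8.2 turned to -0.0076 with 1 value per gene, an average over its probes. A filter on signal over background was not run, since no signal level was used, and leaving out arrays of different sex was not run, since 2 arrays would stay. Where both arrays of a wild type were left out, the block's correlation was that of all 6 arrays.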

Other observations

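The test on arrays 1 and 4 and the sorting of splits by wild type were chosen only after the results were seen, and the other tests here were set before their results. Of 13531 probes with values on all 6 arrays, 765 (5.65%) had the same sign on all. The arrays were turned by each of the 10 splits into 3 and 3, the real one included, but only 3 of the others keep the 2 arrays of each wild type opposed as in the real one, with shares of 2.59% to 3.87%, while the 6 that do not gave 0.64% to 1.66%. For probes with an unadjusted p under 0.05 in the fit without a block, the real split gave 1119, the 3 comparable splits 884 to 1151, and the remaining splits 396 to 695. The number of gene lists called with the preset correlation was 2 in the real split and at most 2 in the others. With 10 splits, of which 4 are comparable, no share under 0.05 can be reached. Apart from an overall sign, every other split keeps most arrays in the real direction. Part of a genotype effect would therefore remain in those splits.

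A hypothesis was that alleles carried along with the targeted Mest locus, or local regulation, shift genes near it on chromosome 6. The 100 measured genes nearest to Mest, by the gene order of assembly GRCm38.p6, had a mean absolute z of 0.88, against a median of 0.83 over 10000 random sets of 100 genes (permutation p = 0.198). Of these genes 47 lay above 0 and 53 below, and their mean log2 ratio was -0.057. The test gave no evidence for a local shift and does not exclude a small one.

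The wild-type label of array 1 conflicts with the design text. If arrays 1 and 4 share a wild-type cortex, their residuals may correlate. Their residual correlation over probes was 0.069, while the pairs 2 and 5 and 3 and 6, whose labels agree, gave 0.23 and 0.13, and pairs with different wild types and opposite dye orientation ranged from -0.17 to 0.096. Whether array 1 holds wild type 2 cannot be told apart from another wild type by this value.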
